A study of Mus musculus with 6 samples.

How the data were processed

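RAW264.7 mouse macrophages were cultured for 3 days on pristine PEEK or on a modified PEEK surface, 3 samples each, per the labels. Total RNA was extracted with Trizol, and biotin-labelled cDNA from 250 ng was hybridised to Affymetrix arrays, per the labels' protocols. The values deposited by the authors are log2 signals per probe set. RMA, a method of background correction, quantile normalization and probe summary, is named in the submitters' processing notes without a version or role. The log2 scale was inferred from the values, which run from 0.941 to 12.4 with nearly equal quantiles on all 6 arrays. Quantile normalization gives arrays nearly the same overall distribution, so a change in total RNA per cell would not be seen where it was applied.

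The value table has 29129 features, of which 6923 are array controls. A gene was named through the platform annotation for 19572 probe sets with 1 gene each; 0 named several genes and 2634 transcript probe sets had no gene name in the table used here. The probe set with the highest mean was kept for the 55 genes with more than 1, none of which had probe sets passing in opposite directions, leaving 19505 genes. The genome build was not given in the sources used here, so no coordinates are printed. There were 0 columns of per-sample values left unused.

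Surfaces were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend, two-sided), on all 6 arrays with no covariate, and p-values were adjusted by the Benjamini-Hochberg method. The moderated test had 4 residual and 4.09 prior degrees of freedom. Genes with an adjusted p under 0.05 were taken as changed. Log2 changes are modified minus pristine PEEK, and folds are powers of 2 of them, which array compression can make smaller than the true ratio at low and very high signal. No filter on dim probes was used.

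A set of 40 gene lists, with 749 measured genes, was fixed before the data were examined, as were the design, the rule for named genes and most alternatives. Some genes stand in several lists. List shifts were tested with limma's camera (preset correlation 0.01), which compares a list with all other genes, with camera using an estimated correlation, and with fry, which tests whether a list's genes move on balance one way or, in its mixed form, change in either direction. Camera weighs the mean of the genes' test statistics, so a list can shift while its median change stays near 0. Adjusted p-values for lists are over the 40 lists. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the members of a list only.

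Genes named were the 12 largest rises and the 12 largest falls among genes that passed and whose arrays did not overlap between surfaces, leaving aside predicted genes. From each list came up to 4 members that passed with the largest change and up to 2 at the highest level that did not pass; not every gene picked this way is named in the text. The markers Nos2, Tnf, Il6, Il1b, Cd86, Il10, Arg1, Mrc1 and Cd163 were named whatever their result. Hspa5, Marcksl1, Tpi1, Ccl3 and Cxcl3, and in the closing section the histone family, the prostaglandin genes, Gbp8, Gbp9, Ifnb1, S100a8 and S100a9, were chosen after their values were seen or for a test.

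A background was set after seeing the data at the 95th percentile (3.72 log2) of the mean signals of 1412 olfactory and vomeronasal receptor genes, few of which a macrophage uses. Where 1 surface lay below it, the fold is a bound, the brighter mean over the background; where both did, no fold is given. Array controls were compared between surfaces with an exact permutation test. The spikes were 24 poly-A and 18 hybridisation probe sets; when the poly-A spikes were added to the RNA is not given in the sources used here.

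Alternatives were quantile normalization again, centring on array medians, leaving out the lowest 25% or 50% of genes by mean signal, the mean of a gene's probe sets, all probe sets tested, an intensity trend with or without robust fitting, array weights, the replicate number as a block, an ordinary t statistic per gene, and leaving out each array in turn. Scaling to the poly-A spikes and leaving out genes below the background on both surfaces were added after seeing the data.

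The test was tested on simulated data for this comparison, with 19505 genes, 3 arrays per group and 200 changed genes in 5 runs. It recovered 20.6% of genes changed by 0.5 on the log2 scale, 71.6% of those changed by 1 and 99.4% of those changed by 2, with 3.04% of calls false. The 200 changed genes are far fewer than the 2027 that passed in the data. The adjustment is then stricter in the simulation, so these recovered shares need not hold for the data. A list shifted by 0.3 was found in 5 of 5 runs. Each simulated gene varied independently, so these runs do not show how the list test behaves where genes of a list vary together.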

Results

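Total RNA from RAW264.7 cells, a mouse macrophage cell line, was profiled on 6 Affymetrix expression arrays after 3 days of culture on polyetheretherketone (PEEK), a polymer used in bone implants. There were 3 arrays from cells on the pristine polymer, which served as the control, and 3 from cells on a modified PEEK surface, whose modification is not described in the sources used here. The deposited values were log2 signals between 0.941 and 12.4, with array medians over genes between 4.98 and 5.10. A gene signal above 3.72, the 95th percentile of olfactory and vomeronasal receptor genes, was present for 65.5% to 68.2% of genes per array. The number of arrays limits the precision of every value. Nothing in the labels says that the 3 samples of a surface came from independent experiments, so the p-values measure only the spread between these samples, which may be technical.

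The question addressed was how culture on the modified surface changed the transcriptome of the macrophages relative to pristine PEEK. By camera, the S phase and DNA replication list (22 of 26 genes higher), the G2 and mitosis list (26 of 26) and the cholesterol biosynthesis list (15 of 19; adjusted p = 0.105 with an estimated correlation) were shifted higher on modified PEEK. The interferon-stimulated list (22 of 30 genes lower; adjusted p = 0.146 with an estimated correlation), the oxidative stress list (11 of 24) and the metal and iron handling list (9 of 16, with 1 higher) were shifted lower. With an estimated correlation, the S phase, mitosis, oxidative stress and metal lists each had an adjusted p of 0.0494, just under 0.05. Lcn2, encoding the iron-siderophore binding protein lipocalin 2, fell by 6.10 on the log2 scale to 3.78. That level is next to the background of 3.72, so the size of this fall is close to a lower bound. Mmp12, encoding macrophage elastase, fell by 5.50, a 45.4-fold difference. Hpgd, encoding the enzyme that inactivates prostaglandins, rose by 3.07, which is 8.41-fold (adjusted p = 4.43e-05, higher on 3 of 3 arrays).

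Of 19505 genes tested with limma, 2027 (10.4%) differed between the surfaces at an adjusted p under 0.05, with 1023 higher and 1004 lower on modified PEEK. A difference of at least 2-fold was found for 376 of them, 194 higher and 182 lower. The groups did not overlap for 5619 genes (28.8%, where chance gives 10%), including all 2027 that passed. Correlations between arrays over genes, which are not independent replicates, were 0.991 to 0.995 within a surface and 0.985 to 0.988 between surfaces, and the first principal component, with 53.4% of the variance, separated the surfaces. Leaving out 1 array lowered the count to 1241 without pristine PEEK replicate 1, 1239 without pristine PEEK replicate 2, 1142 without pristine PEEK replicate 3 and 1300 without modified PEEK replicate 3. With an intensity trend in the variance model the count was 3305, and with the genes below the median signal left out 1467 genes were higher and 1521 lower. Poly-A spike-in probe sets averaged 6.96 ± 0.15 on pristine and 6.71 ± 0.14 on modified PEEK (SD, n = 3; exact permutation test, two-sided p = 0.2, with 0.1 the smallest possible). With the arrays scaled to these spikes, a choice made after seeing the data, the median change of all genes moved from 0.0088 to 0.26 and the genes passing were 1575 higher and 290 lower. Hybridisation spike probe sets also averaged lower on modified PEEK, at 9.14 ± 0.11 against 9.31 ± 0.08 (SD, n = 3; exact permutation test, two-sided p = 0.2). The difference was -0.17, beside -0.25 for the poly-A spikes. A lower spike signal was therefore not specific to the poly-A spikes, and its cause was not tested.

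The largest rises after Hpgd were those of Htr1b, a serotonin receptor gene (1.90 ± 0.18 SE), and Cx3cr1, the fractalkine receptor gene (3.69-fold, reaching 8.89 ± 0.08; SD, n = 3). The linker histone genes H1f1 and H1f5 rose by 1.87 each, and the histone gene H2bc3 by 1.70. Igf1, encoding insulin-like growth factor 1, rose from 9.28 ± 0.14 to 11.07 ± 0.08 (3.46-fold, adjusted p = 0.000122). Lpar6, a lysophosphatidic acid receptor gene, rose by 1.87, Klhl6 by 1.80, Sesn1 by 1.68, Kbtbd11 by 1.66 and Depdc1a by 1.65.

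Among the falls, Lcn2 went from 9.88 ± 0.23 to 3.78 ± 0.32 (SD, n = 3; adjusted p = 3.52e-06), the latter next to the receptor-gene background. Mmp12 went from 10.53 ± 0.16 to 5.02 ± 0.18 (adjusted p = 1.39e-06). The carbonic anhydrase gene Car6 fell by 4.41 (21.3-fold), and the neutrophil-attracting chemokine gene Cxcl2 fell by 3.23 (9.40-fold). Ptgs2, encoding cyclooxygenase 2, fell by 2.51 (5.68-fold). Slc40a1, the iron exporter ferroportin (-2.85), Emp2 (-2.75), Plk2 (-2.72), Atp6v0d2 (-2.43) and the water and glycerol channel gene Aqp9 (-2.42) also fell. Procr, the protein C receptor gene, fell by 3.00 to 3.73, next to the background. Fam171b lay below the background on modified PEEK and was at least 6.08-fold lower.

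**Figure D1:**
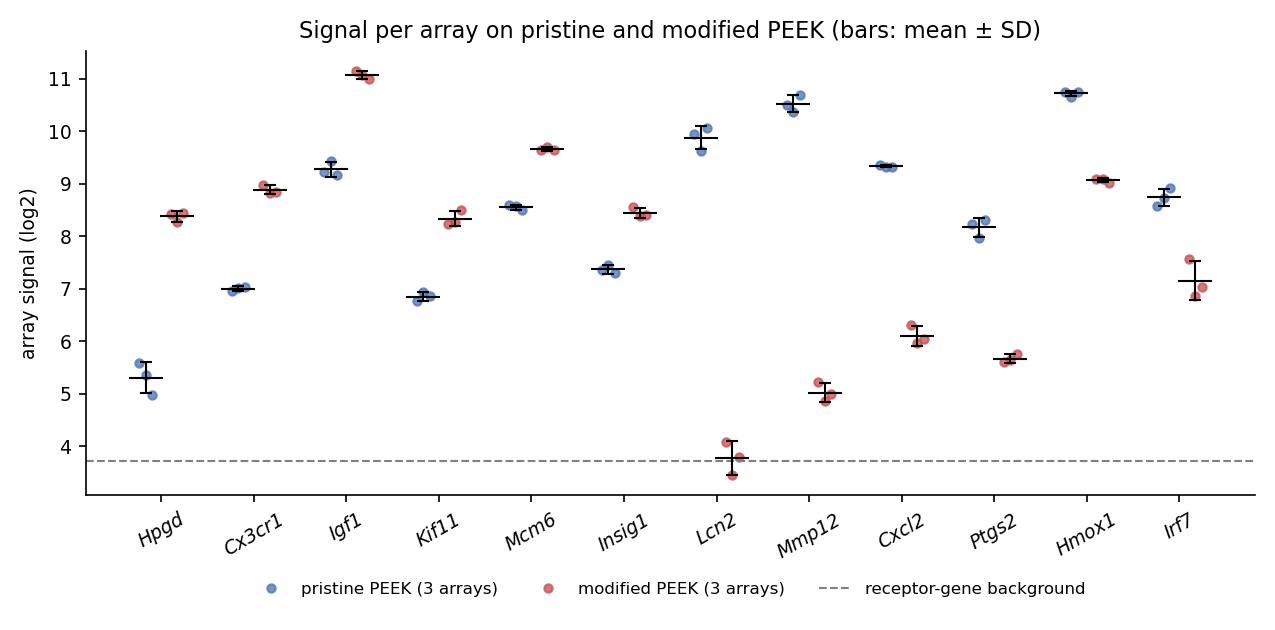
Log2 array signal of 12 genes on each of the 3 pristine PEEK arrays (blue) and 3 modified PEEK arrays (red), with the mean ± SD as black bars and the receptor-gene background of 3.72 as a dashed line. The arrays of the surfaces do not overlap for any gene shown. All were taken from genes that passed, none of which overlapped, so this is no added evidence. Lcn2 on modified PEEK lies next to the background.

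Cell division genes moved in 1 direction. All 26 genes of the G2 and mitosis list were higher (26 adjusted over the list alone), with a median change of 1.27 (camera adjusted p = 4.79e-35, and adjusted p = 0.0494 with an estimated correlation). Examples were the spindle motor genes Kif11 (from 6.85 ± 0.09 to 8.34 ± 0.14; SD, n = 3) and Kif20a (2.79-fold), Hmmr (2.79-fold) and the kinetochore gene Cenpf (2.77-fold). Of 26 S phase and DNA replication genes, 22 were higher and 0 lower (24 and 0 adjusted over the list alone), with a median of 0.72 (adjusted p = 4.62e-21, and adjusted p = 0.0494 with an estimated correlation). The replicative helicase genes Mcm6 (2.15-fold) and Mcm5 (2.12-fold), the origin licensing gene Cdc6 (2.12-fold) and the ribonucleotide reductase gene Rrm1 (2.06-fold) led this list.

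Cholesterol biosynthesis genes were higher in 15 of 19 cases and lower in 0 (17 and 0 adjusted over the list alone), with a median change of 0.64 (camera adjusted p = 3.18e-13; adjusted p = 0.105 with an estimated correlation). Idi1, of the isoprenoid part of the pathway, rose 2.15-fold, and Insig1, which restrains the processing of sterol-regulated transcription factors, rose from 7.37 ± 0.08 to 8.45 ± 0.09 (SD, n = 3; adjusted p = 0.000455). Stard4 rose 1.98-fold and the lanosterol demethylase gene Cyp51 1.92-fold. The number higher was 8 without pristine PEEK replicate 1, 8 without pristine PEEK replicate 2, 9 without pristine PEEK replicate 3 and 9 without modified PEEK replicate 3. Of 18 LXR target and lipid handling genes, 5 were higher and 1 lower (7 and 2 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.0170; adjusted p = 0.349 with an estimated correlation). They included the fatty acid desaturase gene Scd1 (1.80-fold) and the acetyl-CoA carboxylase gene Acaca (1.51-fold), while the lipid droplet gene Plin2 fell by 0.82. This list shift did not pass without pristine PEEK replicate 1 (adjusted p = 0.0675), and 3 of its genes were higher without that array or without modified PEEK replicate 3.

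Interferon-stimulated genes were lower in 22 of 30 cases and higher in 0 (27 and 0 adjusted over the list alone), with a median change of -0.75 (camera adjusted p = 3.57e-21; adjusted p = 0.146 with an estimated correlation). Irf7, a transcription factor of the interferon response, fell from 8.74 ± 0.17 to 7.15 ± 0.37 (SD, n = 3; adjusted p = 0.00127). The oligoadenylate synthetase-like genes Oasl2 (-1.44) and Oasl1 (-1.34) and the interferon-induced gene Ifit1 (-1.33) also fell. Bst2 (-0.49, adjusted p = 0.0533) and Irf9 (-0.33, adjusted p = 0.108) did not pass, but did with an intensity trend (Bst2 adjusted p = 0.00246, Irf9 adjusted p = 0.0257). Scaled to the poly-A spikes, 13 of these genes were lower and the list median was -0.50, or -0.76 relative to all genes.

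Of 18 genes of classical (M1-type) activation, 8 were lower and 0 higher (8 and 0 adjusted over the list alone), with a median change of -0.17 that was 0.0754 when scaled to the spikes and -0.18 relative to all genes (camera adjusted p = 3.30e-06; adjusted p = 0.148 with an estimated correlation). Besides Ptgs2 they included Acod1, the itaconate-producing enzyme gene (3.22-fold lower), the costimulatory ligand genes Cd80 (2.73-fold lower) and Cd86 (from 6.18 ± 0.06 to 4.87 ± 0.32; SD, n = 3) and the cytokine gene Il23a, which was at least 2.09-fold lower because it lay below background on modified PEEK. Nos2, the inducible nitric oxide synthase gene, was at least 1.66-fold lower for the same reason (adjusted p = 0.00634). Tnf fell by 0.55, from 10.04 ± 0.08 to 9.49 ± 0.04 (adjusted p = 0.00696), and did not pass when scaled to the spikes (adjusted p = 0.225, the highest of the alternatives). Irf5 (0.15, adjusted p = 0.541) did not pass. The mean change of the classical activation list was -0.64, larger than its median.

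The alternative (M2-type) activation list of 22 genes showed no shift by camera (median -0.0286, adjusted p = 0.193), with 1 gene higher and 2 lower (2 and 3 adjusted over the list alone). It did pass fry, which tests whether its genes moved on balance one way (adjusted p = 0.0251). Myc (-1.49) and Il1rn, the interleukin-1 receptor antagonist gene (-1.41), fell. Mrc1, the mannose receptor gene, passed as higher (adjusted p = 0.0375) at levels below the background on both surfaces, 2.81 ± 0.49 and 3.71 ± 0.07 (SD, n = 3). The call for Mrc1 held among the fits without 1 array only when pristine PEEK replicate 2 was left out. Without pristine PEEK replicate 1 or 3, or modified PEEK replicate 1, 2 or 3, its adjusted p did not pass and reached 0.131. Of the other polarisation markers, 5 did not pass: Arg1 (3.16 ± 0.21 and 3.29 ± 0.20), Il10 (3.37 ± 0.14 and 3.03 ± 0.11), Il1b (3.34 ± 0.11 and 3.30 ± 0.38) and Il6 (2.05 ± 0.24 and 1.85 ± 0.03) lay below background on both surfaces, and Cd163 lay next to it (3.80 ± 0.28 and 3.84 ± 0.21).

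Chemokine genes were lower in 5 and higher in 1 of 20 cases (5 and 1 adjusted over the list alone). The list was not shifted by camera (adjusted p = 0.106) but passed fry (adjusted p = 0.0158). Besides Cxcl2, the macrophage inflammatory protein genes Ccl4 (3.16-fold) and Ccl3 (2.15-fold), Ccl2 (2.21-fold) and Cxcl3 (1.72-fold) were lower, and Cxcl16 was 2.33-fold higher. Of 9 chemokine receptor genes, 2 were higher and 1 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.945): Cx3cr1 and Cxcr4 (1.64-fold) were higher, and Ccr1 fell by 2.32. The call for Cxcr4 was lost without pristine PEEK replicate 1, 2 or 3 or modified PEEK replicate 3, with an adjusted p of up to 0.0912. Without modified PEEK replicate 1, 2 receptor genes were lower.

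NF-kB target and feedback genes were lower in 8 of 18 cases and higher in 0 (9 and 1 adjusted over the list alone), with a median change of -0.29 (camera adjusted p = 0.000111; adjusted p = 0.20 with an estimated correlation). Ier3 (-1.18) and Nfkbiz, encoding the nuclear cofactor IkB-zeta (-1.01), and the inhibitor gene Nfkbib (-0.81) fell, while Birc3 (9.91 ± 0.08 and 10.03 ± 0.06; SD, n = 3) did not pass. The number lower was 5 without pristine PEEK replicate 2, 3 without pristine PEEK replicate 3 and 3 when scaled to the spikes. Toll-like receptor signalling genes showed no shift (20 measured, 1 higher and 2 lower, 5 and 6 adjusted over the list alone; camera adjusted p = 0.934). Tlr8 rose 2.53-fold, Ly96 fell by 0.47 and Tab2 fell by 0.37. Without pristine PEEK replicate 3 the call for Ly96 was lost (adjusted p = 0.0669), and that for Tab2 was lost when any 1 of the 6 arrays was left out (adjusted p from 0.0597 to 0.118). Of 13 inflammasome and pyroptosis genes, 1 was higher and 2 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.634). Casp4, an inflammatory caspase gene, fell by 1.08. Nlrp3 (-0.43) lost its call without pristine PEEK replicate 1, 2 or 3 or modified PEEK replicate 2 or 3 (adjusted p up to 0.0943), and Nlrc4 (0.62) without any array but modified PEEK replicate 2 (up to 0.158).

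Genes of the NRF2 and oxidative stress list were lower in 11 of 24 cases and higher in 0 (14 and 0 adjusted over the list alone), with a median change of -0.38 (camera adjusted p = 1.90e-08, and adjusted p = 0.0494 with an estimated correlation). Hmox1, encoding haem oxygenase 1, fell from 10.72 ± 0.05 to 9.07 ± 0.04 (SD, n = 3; 3.15-fold, adjusted p = 6.50e-05). The cystine transporter gene Slc7a11 (-1.19), the glutathione synthesis gene Gclm (-1.10) and the NADPH-producing enzyme gene Me1 (-1.07) fell as well. Of 16 metal and iron handling genes, 9 were lower and 1 higher (10 and 1 adjusted over the list alone), with a median of -0.49 (adjusted p = 2.99e-07, and adjusted p = 0.0494 with an estimated correlation). Besides Slc40a1, the copper transporter gene Slc31a2 (-1.04), Slc11a1 (-0.86) and the metallothionein gene Mt2 (-0.79) fell. The higher gene of this list passed without modified PEEK replicate 2 and in none of the other fits without 1 array, where 0 genes of the list were higher. Scaled to the spikes, 7 genes of the oxidative stress list and 3 of the metal list were lower.

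Integrated stress response and amino acid supply genes were lower in 9 and higher in 1 of 27 cases (19 and 1 adjusted over the list alone), with a median change of -0.33 (camera adjusted p = 6.27e-09; adjusted p = 0.154 with an estimated correlation). Ppp1r15a (-1.49), Ddit3 (-1.13) and Trib3 (-0.91) fell. The single higher gene was lost, leaving 0, in each fit without 1 array except that without modified PEEK replicate 1. Of 18 unfolded protein response genes, 5 were lower and 0 higher (5 and 0 adjusted over the list alone), with a median of -0.0742 that was 0.17 when scaled to the spikes and -0.0830 relative to all genes (adjusted p = 0.0313; adjusted p = 0.20 with an estimated correlation). These were Dnajb9 (-0.83), Ern1 (-0.76), Sel1l (-0.56), Hyou1 (-0.45) and the chaperone gene Hspa5 (-0.37). Passed or not, 9 of the 18 genes changed upward and 9 downward, with a mean of -0.18, so the list shift came from part of the list. The list shift was lost without pristine PEEK replicate 2 (adjusted p = 0.0556) and modified PEEK replicate 2 (0.0911), and 3 of its genes passed without pristine PEEK replicate 1, 2 or 3 or modified PEEK replicate 3. Hspa5 lost its call without any 1 of the 6 arrays (adjusted p from 0.0674 to 0.136), and Hyou1 without pristine PEEK replicate 1, 2 or 3 or modified PEEK replicate 3 (up to 0.0823). None of 13 heat shock genes passed (camera adjusted p = 0.498; 0 also adjusted over the list alone).

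Of 20 p53 target and apoptosis genes, 7 were lower and 1 higher (8 and 1 adjusted over the list alone), with a median change of -0.25 that was 0.000680 when scaled to the spikes and -0.26 relative to all genes (camera adjusted p = 1.89e-05; adjusted p = 0.148 with an estimated correlation). Besides Plk2, the growth arrest gene Gadd45a (-1.48) and Trp53inp1 (-0.96) fell, while Sesn1 rose. Immediate early genes were lower in 11 and higher in 1 of 22 cases (12 and 1 adjusted over the list alone), with a median of -0.36 (adjusted p = 4.50e-05; adjusted p = 0.179 with an estimated correlation). Besides Myc, Dusp5 (-1.09) and Fosl1 (-1.03) fell, whereas Fos rose from 7.02 ± 0.02 to 7.99 ± 0.04 (SD, n = 3; adjusted p = 0.000425). The number lower was 6 without pristine PEEK replicate 1, 5 without each of pristine PEEK replicates 2 and 3 and modified PEEK replicate 3, and 4 when scaled to the spikes; 2 genes were higher without modified PEEK replicate 2.

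Lysosome and autophagy genes were lower in 9 of 29 cases and higher in 0 (16 and 2 adjusted over the list alone), with a median change of -0.25 (camera adjusted p = 1.52e-06; adjusted p = 0.159 with an estimated correlation). The autophagy receptor gene Sqstm1 (-1.06) and the cathepsin gene Ctsl (-0.58) fell. The number lower was 5 without pristine PEEK replicate 1, 4 without pristine PEEK replicate 2, 5 without pristine PEEK replicate 3 and 1 when scaled to the spikes. Of 21 osteoclast differentiation and cell fusion genes, 6 were lower and 1 higher (7 and 4 adjusted over the list alone), with a median of -0.24 that was 0.00414 when scaled to the spikes and -0.25 relative to all genes (adjusted p = 0.0379; adjusted p = 0.349 with an estimated correlation). They included the proton pump gene Atp6v0d2, Acp5, encoding tartrate-resistant acid phosphatase (2.65-fold), and the kinase gene Src (2.08-fold). The osteoclast list shift was lost without pristine PEEK replicate 1 (adjusted p = 0.0975) and modified PEEK replicate 3 (0.0748), and its 1 higher gene passed only without modified PEEK replicate 2, with 0 higher in the other fits without 1 array.

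Matrix and proteolysis genes were lower in 7 and higher in 1 of 23 cases (8 and 1 adjusted over the list alone), with a median change of -0.13 that was 0.12 when scaled to the spikes and -0.14 relative to all genes (camera adjusted p = 0.00509; adjusted p = 0.167 with an estimated correlation). The mean change of the list was -0.48, larger than its median. Besides Mmp12, the urokinase receptor gene Plaur fell by 1.25. The higher gene of this list was lost, leaving 0, without pristine PEEK replicates 2 or 3 and without modified PEEK replicates 1 or 3. Of 25 integrin and adhesion genes, 6 were lower and 1 higher (7 and 1 adjusted over the list alone), with a median of -0.22 that was 0.0303 when scaled to the spikes and -0.23 relative to all genes (adjusted p = 0.000842; adjusted p = 0.148 with an estimated correlation). Itgax, encoding CD11c (-1.34), the focal adhesion gene Zyx (-0.90) and Itgb7 (-0.83) fell, and Itga4 rose 1.89-fold.

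Actin cytoskeleton and motility genes were lower in 4 and higher in 1 of 34 cases (4 and 1 adjusted over the list alone), with a median change of -0.0522 that was 0.20 when scaled to the spikes and -0.0610 relative to all genes (camera adjusted p = 0.0237; adjusted p = 0.305 with an estimated correlation). Rhoc (-1.28, limma adjusted p = 0.000212) and Rhob (-0.71, adjusted p = 0.00712) fell, as did the actin crosslinker gene Actn1 (-0.65) and Marcksl1 (-0.41). Tagln2 rose by 0.47, with its call lost without pristine PEEK replicate 1 or 3 (adjusted p up to 0.0658). Marcksl1 kept its call only without modified PEEK replicate 2 among the fits without 1 array (pristine PEEK replicate 1, 2 or 3 or modified PEEK replicate 1 or 3 left out, adjusted p up to 0.151). Of 15 mechanosensing and YAP/TAZ target genes, 3 were lower and 0 higher (5 and 1 adjusted over the list alone) without a list shift (adjusted p = 0.221). The 3 were Lats2 (-0.93), Axl (-0.79) and Trpv2 (-0.47). Lats2 lost its call without pristine PEEK replicate 1, 2 or 3 or modified PEEK replicate 1 or 2 (adjusted p up to 0.138). Axl lost it without pristine or modified PEEK replicate 3 (up to 0.0549), and Trpv2 without pristine PEEK replicate 1, 2 or 3 or modified PEEK replicate 2 or 3 (up to 0.144). The number lower was 0 without pristine PEEK replicate 3 and 1 without each of pristine PEEK replicates 1 and 2 and modified PEEK replicates 2 and 3.

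Osteogenic and angiogenic factor genes showed no shift (23 measured, camera adjusted p = 0.424). Of them, 2 were higher and 5 lower (2 and 6 adjusted over the list alone). Igf1 had the largest rise, and Angpt2 also rose (0.73, limma adjusted p = 0.0208). Osm (-1.36, limma adjusted p = 0.0104) and Vegfa (-0.49, adjusted p = 0.0321) were among the genes that fell. The number lower was 1 without pristine PEEK replicate 3, 2 without pristine PEEK replicate 2 or modified PEEK replicate 3, and 3 without pristine PEEK replicate 1 or modified PEEK replicate 1. The number higher was 1 without pristine PEEK replicate 1 or 3 or modified PEEK replicate 1 or 3. Macrophage identity genes showed no shift either (20 measured, 2 higher and 4 lower, 3 and 5 adjusted over the list alone; camera adjusted p = 0.945). Ly86 rose by 0.84, and the high-affinity antibody receptor gene Fcgr1 (-0.85), Csf2ra (-0.65) and Itgam (-0.59) fell. Of 27 complement and phagocytic receptor genes, 7 were lower and 2 higher (11 and 3 adjusted over the list alone), with a median of -0.12 that was 0.13 when scaled to the spikes and -0.13 relative to all genes (adjusted p = 0.0493; adjusted p = 0.408 with an estimated correlation). Clec4e, a lectin receptor gene, fell by 0.66. This list kept its shift only without pristine PEEK replicate 1; the adjusted p was 0.0951 without pristine PEEK replicate 2, 0.0941 without pristine PEEK replicate 3, and 0.0535, 0.0569 and 0.0925 without modified PEEK replicates 1, 2 and 3. Its lower genes numbered 4 without pristine PEEK replicate 1 or 2 and 3 without pristine PEEK replicate 3 or modified PEEK replicate 3, and 0 were higher in any fit without 1 array. Of 18 antigen presentation genes, H2-T23 fell by 0.69 and 0 were higher (1 and 0 adjusted over the list alone; camera adjusted p = 0.0969); without modified PEEK replicate 1, 2 were lower and 1 higher.

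Energy metabolism genes went both ways. Of 21 hypoxia response genes, 5 were higher and 6 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.953), with Pdk1 (0.94) rising and Hilpda (-0.90), the glucose transporter gene Slc2a1 (-0.87) and Ndrg1 (-0.86) falling. Of 15 glycolysis genes, 4 were higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.149). Those higher were Aldoc (1.56-fold), Hk2 (1.55-fold), Tpi1 (1.51-fold) and Pfkl (1.57-fold), the last with its call lost without pristine PEEK replicate 1 or 3 or modified PEEK replicate 1 or 2 (adjusted p up to 0.0749). The 26 oxidative phosphorylation genes had a median change of 0.13 (camera adjusted p = 0.0249; adjusted p = 0.452 with an estimated correlation), with 1 higher and 0 lower (0 and 0 adjusted over the list alone). That gene, Cox6c (0.41), lost its call without any 1 of the 6 arrays (adjusted p from 0.0557 to 0.120), and the list shift was lost without pristine PEEK replicate 1 (0.150) or modified PEEK replicate 1 (0.106). Of 21 ribosome biogenesis genes, 3 were higher and 0 lower (6 and 0 adjusted over the list alone), with a median of 0.10 (adjusted p = 0.0371; adjusted p = 0.368 with an estimated correlation). They were Dkc1 (0.61), Polr1b (0.36) and Nolc1 (0.35); 1 passed without modified PEEK replicate 1 and 0 without any of the other arrays, with an adjusted p of up to 0.164. The ribosome biogenesis shift was lost without pristine PEEK replicate 1 (0.164), modified PEEK replicate 1 (0.0787) and modified PEEK replicate 3 (0.0748). None of 19 cytoplasmic ribosomal protein genes passed (camera adjusted p = 0.634; 0 adjusted over the list alone).

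Markers of other cell types were measured with 9 fibroblast, 9 osteoblast, 9 endothelial, 10 epithelial, 11 lymphocyte and 11 neutrophil and mast cell genes. None passed in limma's test (0 also adjusted over each list alone), and no list shifted, with camera adjusted p of 0.674, 0.219, 0.460, 0.272, 0.945 and 0.945 in that order. Over the same order, 4, 4, 3, 7, 4 and 3 of the genes lay above the background on a surface. Without modified PEEK replicate 1, 1 epithelial and 1 lymphocyte gene were higher, and without pristine PEEK replicate 1, 1 neutrophil and mast cell gene was higher.

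**Figure D2:**
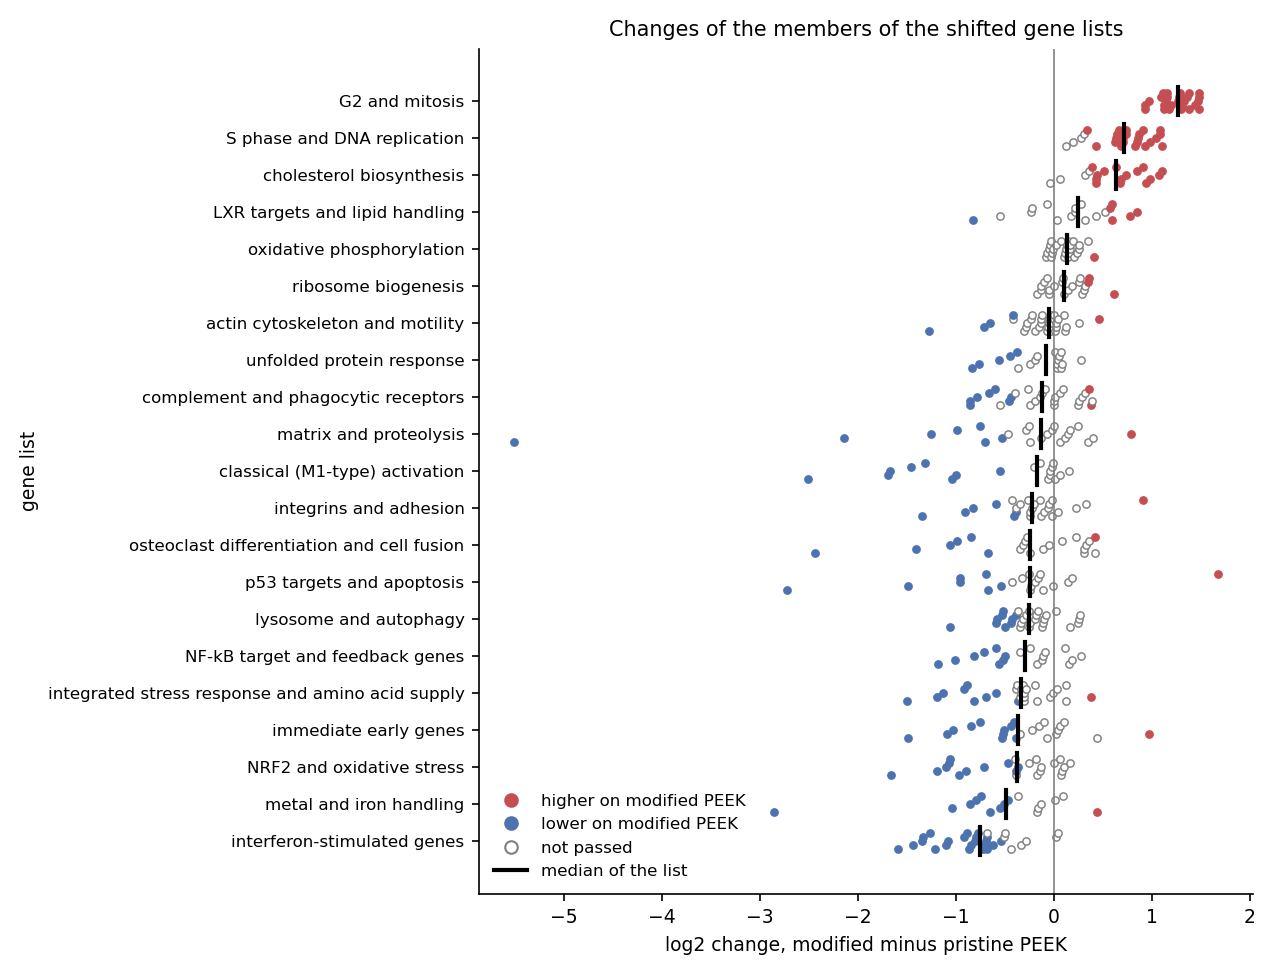
Log2 change (modified minus pristine PEEK, means of 3 arrays each) of every measured gene in the 21 shifted gene lists, with filled red points higher, filled blue points lower, open points not passed and black bars at the list medians. The G2 and mitosis genes all lie above 0, with a median of 1.27, and the interferon-stimulated genes have a median of -0.75. Scaled to the poly-A spikes, the classical activation, p53, integrin, actin, osteoclast, matrix, unfolded protein response and complement medians lie above 0. That scaling raises all genes on modified PEEK, and relative to all genes these medians stay below 0.

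Calls of other named genes ended under another setting. Scaled to the poly-A spikes, those of Axl (adjusted p = 0.0551), Lats2 (0.0570), Mt2 (0.0664), Ern1 (0.0884), H2-T23 (0.102), Cxcl3 (0.11), Actn1 (0.119), Clec4e (0.121), Csf2ra (0.144), Ctsl (0.187), Itgam (0.213), Sel1l (0.234), Trpv2 (0.318), Ly96 (0.335), Hyou1 (0.401), Nlrp3 (0.410), Marcksl1 (0.517), Tab2 (0.595) and Hspa5 (0.597) were lost. With an ordinary t statistic per gene, those of Trp53inp1 (0.0545), Me1 (0.0577), Dnajb9 (0.0657), Cxcl3 (0.0661), Nos2 (0.0712), Src (0.0847), Axl (0.0850), Marcksl1 (0.0856), Fosl1 (0.0865), Pfkl (0.0985), Trpv2 (0.11), Cxcr4 (0.133), Dkc1 (0.160), Nlrc4 (0.176), Mrc1 (0.186) and Lats2 (0.199) were lost. Normalizing by quantiles again ended those of Dkc1 (0.0501) and Marcksl1 (0.0587), array weights that of Lats2 (0.0660), and centring the arrays those of Cox6c (0.0580), Polr1b (0.0660) and Nolc1 (0.0776).

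List shifts and counts also moved with the setting. The actin shift was lost with spike scaling (adjusted p = 0.0711) and with the lowest 50% of genes by signal left out (0.0542). The complement shift was lost with quantile normalization again (0.0689) and with that 50% left out (0.0693), and the osteoclast shift with the lowest 25% (0.0573) or 50% (0.117) left out. The ribosome biogenesis shift was lost with the lowest 25% (0.0511) or 50% (0.0592) left out. The unfolded protein response shift was lost with quantile normalization again (0.0514), with the lowest 25% (0.0537) or 50% (0.0863) left out, and without genes below background (0.0566). With an intensity trend, the numbers lower were 21 for the integrated stress response, 19 for lysosome, 11 for complement, 10 for integrins, 8 for actin, 6 for Toll-like receptor signalling, 6 for antigen presentation and 4 for the inflammasome. The numbers higher were then 8 for LXR targets, 8 for ribosome biogenesis, 6 for oxidative phosphorylation, and 5 each for the osteoclast list, Toll-like receptor signalling and macrophage identity, and 2 cytoplasmic ribosomal protein genes were higher, 2 lower and 1 heat shock gene higher. With an ordinary t statistic, 9 cholesterol genes and 3 LXR target genes were higher, and 7 immediate early, 2 osteogenic and 0 mechanosensing genes were lower. With array weights, 1 epithelial and 1 lymphocyte marker passed as higher.

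By camera with a preset correlation, 21 of the 40 lists were shifted, 6 higher and 15 lower on modified PEEK. With an estimated correlation 4 held: G2 and mitosis, S phase, oxidative stress, and metal handling. These 4 shared the same adjusted p, 0.0494, just under the threshold of 0.05. It was set by the largest of their unadjusted p-values (0.00494, S phase, camera with an estimated correlation), so the 4 passed only together. The direction of the median differed from that of the mean for macrophage identity (0.0338 and -0.0235, test lower), Toll-like receptor signalling (-0.0744 and 0.0314, test lower), chemokine receptors (0.0343 and -0.0167, test higher) and lymphocyte markers (-0.0882 and 0.0176, test higher), none of which was shifted. Scaled to the poly-A spikes, the numbers of genes lower also moved to 4 for p53 targets, 3 for integrins, 1 for actin, 3 for matrix, 1 for the unfolded protein response, 2 for complement, 3 for hypoxia, 1 for macrophage identity, 1 for osteogenic factors, 1 for the inflammasome, and 0 for mechanosensing, Toll-like receptor signalling and antigen presentation. The numbers higher moved to 4 for the osteoclast list, 4 for Toll-like receptor signalling, 5 for ribosome biogenesis, 2 for the alternative activation list, 2 for immediate early genes, 2 for the inflammasome, and 1 each for mechanosensing and epithelial markers.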

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

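The tests of neutrophil RNA and of endotoxin-type stimulation, and the splits for the gene counts, were chosen only after the results were seen. The others were written before their own outcomes were seen. The cell cycle and interferon patterns they address are results, however, and the background used for Ifnb1 was set after seeing the data.

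Outside the named genes, 2634 transcript probe sets without a gene name were tested, and 83 were higher and 84 lower on modified PEEK. They drew attention because no gene named above covers them; they entered only the alternative in which all probe sets were tested. The largest rises were those of TC1300002543.mm.2 (1.23) and TC1600001380.mm.2 (1.22), and the largest falls were those of TC1700000070.mm.2 (-2.50) and TC0500001412.mm.2 (-2.46).

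All 26 G2 and mitosis genes, with a median of 1.27, were higher on modified PEEK. The tables argue against a bias of the arrays at that signal level, since the highest median among 10000 random lists matched on level was 0.26. A larger share of cycling cells is consistent with 70.6% of the centromere protein genes outside the lists being higher (12 of 17, with 0 lower, though only 6 were higher with an ordinary t statistic), and stays a hypothesis. More transcripts per cycling cell would raise these genes too, so both remain open, as does a difference in cell density at harvest, which was not tested.

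The fall of interferon-stimulated genes (median -0.75) was larger than that of any of 10000 random lists matched on level, whose lowest median was -0.20, which argues against a bias at their signal level. Fewer transcripts of interferon beta cannot be told apart from an unchanged level: Ifnb1 went from 4.01 to 3.97 (log2 change -0.0442 ± 0.17 SE, adjusted p = 0.919), close to the background of 3.72. A smaller response to the same interferon remains open and was not tested.

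The inflammation-related genes Lcn2, Mmp12, Cxcl2 and Ptgs2 were among the largest falls on modified PEEK. Neutrophil RNA on the pristine arrays is argued against, since S100a8 and S100a9, abundant in neutrophils, reached at most 3.40 there, below the background of 3.72. RAW264.7 is a macrophage cell line, so neutrophils were unlikely beforehand and this result narrows the causes little. Less stimulation of an endotoxin type on modified PEEK may be involved, but 52.2% of endotoxin-response genes above background (12 of 23, with 0 higher) were lower, between the bounds set for and against it, and cannot be told apart from other causes. Lcn2, Cxcl2 and Ptgs2 stand in that list themselves and count among its lower genes. The share therefore partly restates the fall it was meant to explain. Il1a, Il1b, Il6 and Il10 of the list lay below the background on both surfaces and were left out of the share. Of the 27 genes measured in the list, 24 also stand in the fixed lists, and the endotoxin content of the surfaces was not measured here.

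For the count of changed genes, the 2027 of the real split compare with 0 for the highest of the other splits; for genes changed at least 2-fold, 376 compare with 0, and for shifted lists 21 compare with 14. In each case 1 of the 10 splits, the real one, gave a count as large, and 10 splits are too few for a share under 0.05. The other splits each mix the surfaces, which adds the difference between surfaces to the spread within groups. Their 0 changed genes are therefore little evidence. All of them still called lists, from 4 to 14, so camera with the preset correlation calls lists readily with mixed labels.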

How the results depend on the processing

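The poly-A spike scaling and the filter on genes below background on both surfaces were chosen after seeing the data. Rhoc, Rhob, Osm, Vegfa, Angpt2, Ptgr1, H3c1, H3c14 and H3c15 were not followed singly through the alternatives. Of 127 other named genes that passed, 0 changed direction in 2405 alternative fits, and 146 of those fits no longer passed. The first count is little evidence, since several alternatives change only the test and not the log2 change, and the spike scaling moves all genes by less than the changes that passed. Counts of genes changed, higher and lower were 3305, 1586 and 1719 with an intensity trend, and 3282, 1580 and 1702 with trend and robust fitting. With the lowest 50% of genes by signal left out, 1467 genes were higher and 1521 lower. Leaving out 1 array gave 1142 to 1863 genes changed, 594 to 903 higher and 548 to 1048 lower; these fits have fewer samples. Scaled to the poly-A spikes, 1575 were higher and 290 lower, and 381 and 91 by at least 2-fold, since that scaling raises all genes on modified PEEK. Shifted lists numbered 4 with an estimated correlation and 25 with fry. Alternative activation (fry adjusted p = 0.0251), chemokines (0.0158), chemokine receptors (0.0335) and antigen presentation (0.0128) passed fry but not camera with the preset correlation. Lists passing fry's mixed test, which counts changes in either direction and so is no test of a shift, numbered 34. With the replicate number as a block, 1268 genes changed, 646 higher and 622 lower, and 14 named genes no longer passed; the numbers do not pair the arrays (correlations of deviations -0.171, -0.161 and 0.0685), and not every array matched its own number best. Unpassed changes near 0 turned sign: Il1b was 0.119 with array weights, 0.211 with spike scaling and -0.25 to 0.117 on leaving out 1 array, Cd163 -0.122 to 0.142 on leaving out 1 array, and Il6 0.0441 with spike scaling. Other than for the spike scaling and the fits with fewer samples, the cause was not tested. Signal near the background limits what can be said of Il6, Il1b, Il10, Arg1, Mrc1 and Cd163.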

Other observations

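The gene families described here were chosen after their values were seen. All 52 measured replication-dependent histone genes, whose transcripts are made in S phase, were higher on modified PEEK, with a median change of 1.11 and 50 to 52 higher on leaving out 1 array. H3c1 lay below the background on both surfaces (1.84 ± 0.10 and 2.43 ± 0.22; SD, n = 3), and H3c14 and H3c15 carried identical values, so the 52 are not separate measurements. The near-identical sequences of these genes make single members uncertain. Of 7 replacement and variant histone genes, 3 were higher and 1 lower; the number lower was 0 without pristine PEEK replicate 1, 2 or 3 or modified PEEK replicate 1, and 0 when scaled to the poly-A spikes, where 4 were higher. With an intensity trend 5 were higher and 0 lower.

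Prostaglandin genes went both ways, with 2 higher and 5 lower of 23 measured. Beside the rise of Hpgd (3.07) and of the receptor gene Ptger4 (0.82), and the fall of Ptgs2, the prostacyclin receptor gene Ptgir fell by 2.18 and the receptor gene Ptger2 by 1.65. The synthase gene Ptges fell by 0.78, with its call lost without pristine PEEK replicate 1, 2 or 3 or modified PEEK replicate 1 (adjusted p up to 0.118). Ptgr1 also fell (-0.50, limma adjusted p = 0.0275). The number lower in this family was 3 without pristine PEEK replicate 1, 2 or 3. Scaled to the spikes, 3 were higher and 3 lower, with the call of Ptges lost (adjusted p = 0.132). With an ordinary t statistic 1 was higher and 3 were lower, with the calls of Ptger4 (adjusted p = 0.0579) and Ptges (0.173) lost. Of 6 guanylate-binding protein genes, 4 were lower and 0 higher, with Gbp8 falling by 2.14 and Gbp9 lying below background on modified PEEK. The number lower was 2 without modified PEEK replicate 3 and 3 in the other fits without 1 array, 2 when scaled to the spikes, and 1 with an ordinary t statistic, where the call of Gbp9 was lost (adjusted p = 0.0708), or with the lowest 50% of genes left out.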
